A study of Mus musculus with 6 samples.

How the data were processed

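Cerebellar tissue of wild-type mice and of transgenic mice carrying daDREAM was profiled on Affymetrix GeneChip Mouse Genome 430 2.0 arrays, 3 arrays per genotype and 6 in all. Per the labels' protocols, frozen tissue gave total RNA, RNA quality was assessed before labelling, and biotin-labelled cRNA was hybridised, with each array holding an independent biological replicate. Genotype and replicate number were taken from the sample titles.

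The authors deposited log2 expression values, 1 per probe set and array. Per the submitters' processing notes these came from RMA in the affy package, a procedure that corrects background, equalises the distributions of probe intensities across arrays and summarises the probes of a set on a log2 scale. The versions of both are not given in the sources used here, and scanner files were not used here. The values ran from 2.46 to 13.8, are rounded to 2 decimals and carry no detection call, so a dim probe set could not be separated from background. RMA forces the probe distributions of the arrays to match, which would hide a change shared by most genes and compresses differences of dim probe sets. The medians over all probe sets lay between 5.12 and 5.23 on the 6 arrays, and the interquartile ranges between 2.97 in daDREAM replicate 3 and 3.49 in daDREAM replicate 1.

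The table held 45101 probe sets. The 64 control probe sets were left out of every test, and 45037 were tested. Of these, 34945 have 1 gene symbol in the platform annotation, 932 have several and 9160 have none. The entrez identifiers of 34754 of the probe sets with 1 symbol were found in the RefSeq gene table of assembly GRCm38.p6, used for names and, in 8 genes, chromosomes. Probe sets with several symbols were given no gene name. For gene lists, each of the 18194 genes was represented by its probe set with the highest mean over the 6 arrays.

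Differences are daDREAM minus wild type in log2 units. They were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), with equal array weights and Benjamini-Hochberg adjustment over all tested probe sets at a threshold of 0.05. Confidence intervals are at 95%. Gene lists were fixed before the data were examined: 41 lists covered cell types of the cerebellum, tissues that border it and pathways tied to DREAM, calcium and neuronal activity, and each was kept with at least 3 measured genes. They were tested with camera, the competitive set test of limma, at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry, the rotation test of limma, served as alternatives. Array means of control probe sets and of list scores were compared with a 2-sided exact permutation test, which cannot go below 0.1 with 3 arrays against 3. Correlations over the 6 arrays used exact permutation p-values.

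The genes named were chosen by a rule set before the data were examined. It takes every probe set of Kcnip3 and up to 12 genes per direction past the adjusted threshold with no overlap between genotypes, filled up by the smallest unadjusted p with no overlap where fewer passed. It adds the leading members of each list, 9 genes reported to respond to DREAM, and the most abundant marker of the choroid plexus, blood, brainstem and forebrain lists. Any other gene named was chosen after its values were seen.

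The number of arrays limits the precision: the median standard error of a difference was 0.15 log2 units, and the median 95% interval reached 0.35 to either side, a factor of 1.27. The procedure was tested on simulated data. With changes added to the measured residuals of the 45037 probe sets, limma called 0% of changes of 0.5 log2 units, 35.2% of changes of 1 and 94.8% of changes of 2. The measured differences were removed first, so the added changes carried no sampling error. Every run used the same residuals, so these shares do not include the noise of an estimated difference. With independent noise the shares were 1.19%, 41.2% and 89.4%. Camera called 50 of 50 simulated lists of 20 genes raised by 0.5 and 1 of 50 unmoved lists, with independent noise, so this says nothing of lists whose genes vary together.

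Alternatives listed before the data were examined were the replicate number as a block, limits on mean level, renewed quantile normalization, median centring, a trended and robust variance prior, estimated array weights, each array left out in turn, 1 probe set per gene, the mean of the probe sets of a gene, and lists without probe sets that match several transcripts. Alternatives added after seeing the data were the level of the hybridization controls as a covariate and the side of the main gradient as a block. Another left out daDREAM replicate 3, at the high end of that gradient, and wild-type replicate 2, the lowest wild-type array. It kept daDREAM replicate 1, which had the lowest score of all. Array weights estimated gene by gene were added after the planned default estimate of the weights had not converged and its calls had been seen.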

Results

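The arrays measured steady-state mRNA in the cerebellum of 3 wild-type and 3 daDREAM mice. DREAM, encoded by Kcnip3, is a calcium-binding repressor of transcription that also binds Kv4 potassium channels, and daDREAM is a mutant form that acts as a repressor irrespective of calcium. The comparison asks which cerebellar transcripts differ in its presence. Pearson correlations across probe sets were 0.989 to 0.997 within wild type, 0.973 to 0.990 within daDREAM and 0.981 to 0.993 between genotypes, and these ranges overlapped. Probe sets are not independent replicates in these correlations.

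Kcnip3 itself was measured by 2 probe sets and neither passed the test. Probe set 1418544_at stood at 9.14 ± 0.15 in wild type and 9.23 ± 0.25 in daDREAM (log2, SD, n = 3), a difference of 0.10 with a 95% interval from -0.27 to 0.46. Probe set 1449129_a_at stood at 7.43 ± 0.14 and 7.54 ± 0.16, a difference of 0.11 with an interval from -0.21 to 0.42. Whether either lies in the transgene is not known here, so these values do not check the genotype labels. With the hybridization control level as a covariate, chosen after seeing the data, the difference of 1418544_at was -0.30. With the planned array weights it was 0.36 (limma adjusted p = 0.00103). Those weights did not converge, placed 99.1% of the weight on daDREAM replicate 2 and called 22291 of 45037 probe sets. That adjusted p therefore says little of Kcnip3.

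None of the 9 genes reported to respond to DREAM passed the limma test after adjustment over all probe sets. Slc8a3, a sodium-calcium exchanger, stood at 7.89 ± 0.14 in wild type and 7.72 ± 0.15 in daDREAM (n = 3), a difference of -0.17 with a 95% interval from -0.47 to 0.14. The related exchangers Slc8a1 and Slc8a2 differed by -0.00 and -0.01. Bdnf, a neurotrophin, differed by -0.29 (interval -0.81 to 0.23) and Kcnd2, a Kv4 channel subunit, by -0.18 (interval -0.63 to 0.28). Pdyn, which encodes prodynorphin, differed by -0.04 at a dim level of 3.55 in wild type. The activity-induced genes Fos and Npas4 differed by -0.15 and -0.04, and the pro-apoptotic gene Hrk by -0.01. Npas4 was also dim, at 3.76 in wild type. The interval of Fos was wide, from -1.25 to 0.94.

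As a list, the reported DREAM targets had 16 of 20 measured genes lower in daDREAM, with a mean difference of -0.08, and did not pass camera (adjusted p = 0.148, and adjusted p = 0.892 with an estimated correlation). Its leading member was Mef2c, an activity-dependent transcription factor, at -0.22 (interval -0.59 to 0.15). None of the 20 passed over all genes or adjusted over the list alone. Without daDREAM replicate 3 the mean difference was -0.15 (camera adjusted p = 0.00106) and without wild-type replicate 3 it was -0.13 (camera adjusted p = 0.0423). It was smaller without wild-type replicate 1, at -0.046 (camera adjusted p = 0.546), and without daDREAM replicate 1, at -0.046 (camera adjusted p = 0.602). The list of DREAM family members and Kv4 channel partners had 6 of 9 genes lower and did not pass, with Kcnd3 at -0.19.

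No single probe set passed the test across the genome. Of 45037 probe sets, 0 reached an adjusted p under 0.05 with limma, where the smallest adjusted p was 0.998, and a trended and robust variance prior also gave 0. At an unadjusted p under 0.05 there were 817, of which 499 were higher and 318 lower in daDREAM, 1.81% of those tested where chance gives 5%. The excess of higher probe sets depended on scaling: after median centring 375 of 772 were higher and 397 lower, and after renewed quantile normalization 706 of 1361 were higher and 655 lower. The genotypes did not overlap at 2708 probe sets, 6.01% where chance gives 10%. The median absolute difference was 0.10. Estimated array weights gave 22291 calls by the planned method, which did not converge and placed 99.1% of the weight on daDREAM replicate 2, and 7510 calls when estimated gene by gene, a method chosen after that outcome was seen. Without daDREAM replicate 1 the count at an unadjusted p under 0.05 was 7254, still with 0 calls after adjustment.

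The genes with the smallest unadjusted p among those whose arrays did not overlap did not pass the adjusted test, and their values follow as measurements. On the higher side, Sostdc1, a secreted antagonist of BMP and Wnt signalling, stood at 4.80 ± 0.34 in wild type and 5.88 ± 0.37 in daDREAM (n = 3), a difference of 1.07 with a 95% interval from 0.55 to 1.59. It was the single probe set of 17 differing at least 2-fold whose genotypes did not overlap. Ecrg4, a secreted peptide precursor abundant in choroid plexus, differed by 0.89, and its other 2 probe sets by 0.54 and 0.19. Kl, which encodes klotho, differed by 0.74, Calml4 by 0.51 and Prelp, an extracellular matrix proteoglycan, by 0.51. Cspg5, a neural chondroitin sulfate proteoglycan, differed by 0.45, Amigo1, a neuronal adhesion protein, by 0.48, and Lrp1b, a member of the LDL receptor family, by 0.47. Pphln1 differed by 0.62, Cant1 by 0.52, Marcksl1 by 0.49 and Rabl6 by 0.49. A further probe set of Pphln1 differed by -0.02, 1 of Cant1 by -0.06 and 2 of Rabl6 by -0.04 and -0.13. The other 2 probe sets of Lrp1b differed by 0.07 and 0.02, those of Marcksl1 by 0.05 to 0.33, those of Amigo1 by 0.06 to 0.21, that of Prelp by 0.12 and that of Kl by 0.23.

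On the lower side, Zfp871, a zinc finger gene, stood at 7.22 ± 0.27 in wild type and 6.29 ± 0.53 in daDREAM (n = 3), a difference of -0.93, and its other 2 probe sets differed by -0.26 and -0.47. Aldoa, a glycolytic aldolase, differed by -0.70 at 1 probe set and by -0.12 to 0.07 at the other 4. Mphosph9 differed by -0.68, while 3 of its other 5 probe sets were higher. Ptpn2, a tyrosine phosphatase, differed by -0.58 and all 4 of its probe sets were lower. Il1rap, the accessory protein of the interleukin receptor, differed by -0.57 at 1 probe set and by -0.13 to 0.01 at its other 4. Dnpep, an aspartyl aminopeptidase, differed by -0.54, with 1 of its 5 probe sets higher by 0.19. Dcdc2b differed by -0.54, the splicing factor Rbm17 by -0.49, 4930453N24Rik by -0.46, Arhgap20 by -0.45, the DNA repair gene Fanci by -0.45 and Ly6e by -0.42. The further probe sets of Rbm17 and Ly6e, both brighter, each differed by -0.05. Those of Dcdc2b, Arhgap20 and Fanci differed by -0.32, -0.23 and 0.08, and the further 5 of 4930453N24Rik by -0.16 to 0.02.

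Of the 41 gene lists, 5 passed camera at the preset correlation, 4 higher and 1 lower in daDREAM. With an estimated correlation 0 lists passed, and 0 passed with fry.

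**Figure D1:**
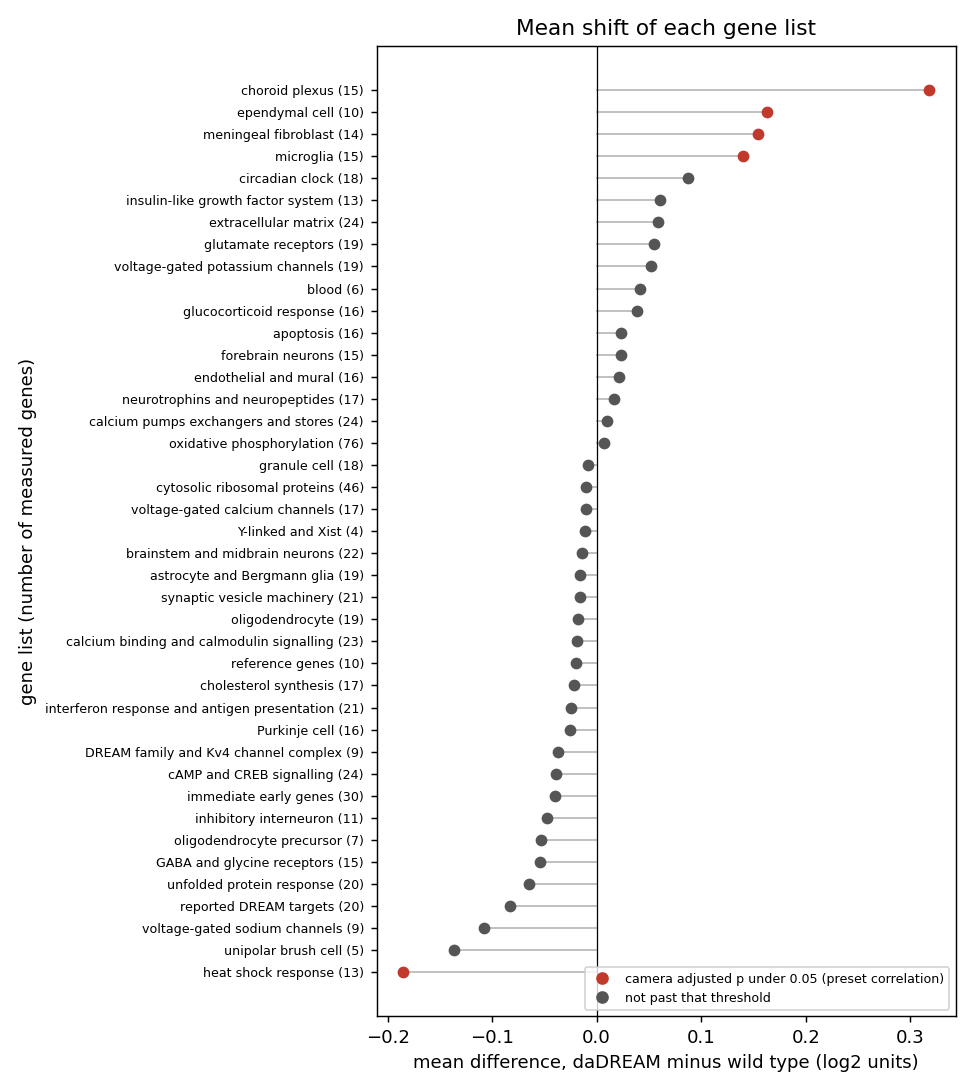
Mean daDREAM minus wild-type difference of each of the 41 gene lists, in log2 units, with the number of measured genes in brackets. Red points mark the 5 lists past camera's adjusted threshold of 0.05 at the preset correlation, with choroid plexus at 0.32 and heat shock response at -0.19.

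Markers of the choroid plexus, the epithelium that secretes cerebrospinal fluid, were higher in daDREAM. Of 15 measured genes 14 were higher, by a mean of 0.32 log2 units or 1.25-fold (camera adjusted p = 6.48e-08, and adjusted p = 0.411 with an estimated correlation). None passed over all genes, and 3 passed limma adjusted over the list alone: Sostdc1 at 1.07 (adjusted p = 0.0166), Calml4 at 0.51 (adjusted p = 0.0166) and Kl at 0.74 (adjusted p = 0.0206). Ttr, the thyroid hormone carrier transthyretin and the most abundant marker of the list, stood at 12.47 ± 0.22 in wild type and 12.90 ± 0.10 in daDREAM (n = 3), and its 4 probe sets differed by 0.43 to 0.65 without overlap. Folr1, a folate receptor named after its value was seen, differed by 0.44. Steap1 was the member with the opposite sign, at -0.18. These signs are those of the brightest probe set of each gene. The other probe set of Steap1 differed by 0.12 and that of Cldn2 by -0.11. For Clic6 the brightest differed by 0.13 and the other by 0.73. The array scores of the list did not overlap between genotypes (exact permutation p = 0.1, the smallest possible with 3 arrays against 3). The mean level of 18 hybridization control probe sets, RNA added in fixed amounts to each array, was 9.15 ± 0.28 in wild type and 10.03 ± 0.51 in daDREAM (n = 3, exact permutation p = 0.2). Over the 6 arrays the correlation of the list score with that level was not below 0.05 after adjustment, at Pearson r = 0.816 (exact permutation p = 0.0639, adjusted p = 0.0852; Spearman rho = 0.714, exact permutation p = 0.136, adjusted p = 0.136; r = 0.851 without the 2 arrays farthest from the median; 4 relations computed). With that level as a covariate, chosen after seeing the data, the choroid plexus shift was 0.23 (camera adjusted p = 0.155). The level partly follows genotype, so here and below a fit with it cannot cleanly separate them.

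**Figure D2:**
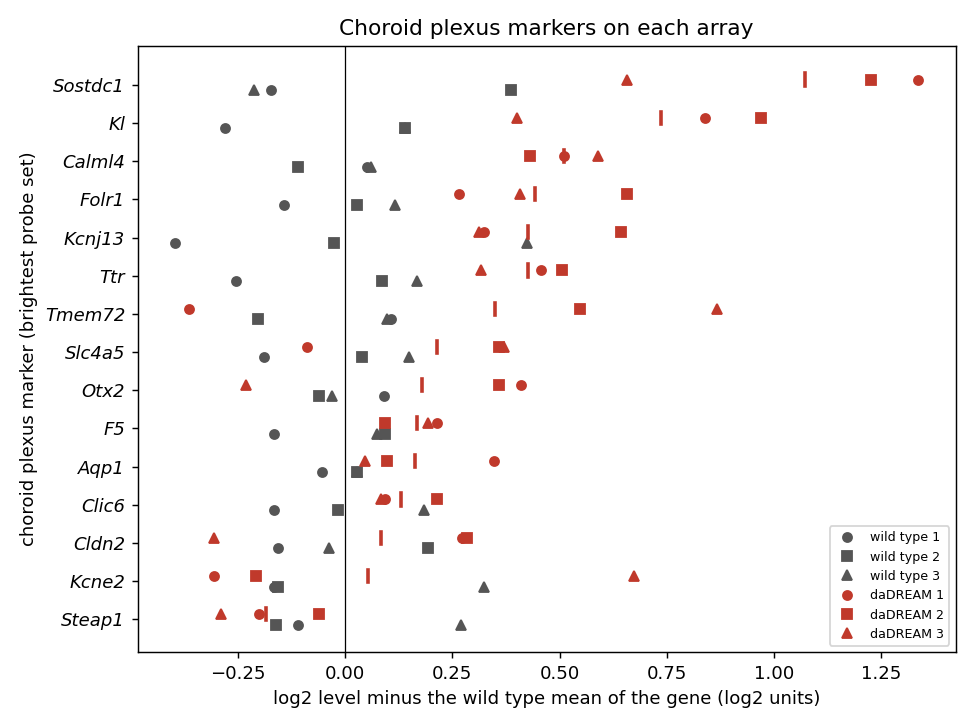
Level of each choroid plexus marker on each array, in log2 units relative to the wild-type mean of that gene, with grey symbols for the 3 wild-type arrays, red symbols for the 3 daDREAM arrays and red bars for the daDREAM mean. Sostdc1 has the largest daDREAM mean, at 1.07, and Steap1 alone has a daDREAM mean below 0.

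Other lists of cell types at the surfaces of the cerebellum also passed. Meningeal fibroblast markers had 12 of 14 genes higher, by a mean of 0.15 (camera adjusted p = 0.00421, and adjusted p = 0.411 with an estimated correlation), led by Igfbp2, an insulin-like growth factor binding protein, at 0.58, and Igf2 differed by 0.32. Ependymal markers, of the ciliated cells that line the ventricles, had 8 of 10 genes higher, by a mean of 0.16 (camera adjusted p = 0.0117, and adjusted p = 0.892 with an estimated correlation), led by Foxj1, a regulator of motile cilia, at 0.31. No member of either list passed over all genes or adjusted over the list alone. Without daDREAM replicate 1 the fibroblast shift was 0.12 (camera adjusted p = 0.353), and with the hybridization control level as a covariate it was larger, 0.25, and did not pass (camera adjusted p = 0.0925). Without daDREAM replicate 3 the ependymal shift was 0.10 (camera adjusted p = 0.203). The ependymal list passed in 2 of the 6 runs that left out 1 array, and its shift was -0.15 with the hybridization control level as a covariate.

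Microglial markers, of the resident macrophages of the brain, had 13 of 15 genes higher, by a mean of 0.14 (camera adjusted p = 0.00421, and adjusted p = 0.411 with an estimated correlation). C1qc, a subunit of complement C1q, differed by 0.32 and led the list. Among members chosen after their values were seen, its partners C1qb and C1qa differed by 0.24 and 0.05, and P2ry12, a purinergic receptor, by 0.30. No member passed over all genes or adjusted over the list alone. Without daDREAM replicate 1 the shift was larger, 0.17, and did not pass (camera adjusted p = 0.0783), and with the hybridization control level as a covariate it was 0.056 (camera adjusted p = 0.807).

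Heat shock genes were lower in daDREAM as a list at the preset correlation. All 13 measured members were lower, by a mean of -0.19 (camera adjusted p = 0.000214, and adjusted p = 0.892 with an estimated correlation). Hspe1, the mitochondrial co-chaperonin, led with -0.29. Among members chosen after their values were seen, the cytosolic chaperone genes Hsp90aa1 and Hsph1 differed by -0.13 and -0.24, and Hspb1, a small heat shock protein, by -0.26. No member passed over all genes or adjusted over the list alone. The array scores of the list overlapped between genotypes (exact permutation p = 0.2), and they ran against the hybridization controls over the 6 arrays (Pearson r = -0.855, exact permutation p = 0.0458, adjusted p = 0.0852; Spearman rho = -0.943, exact permutation p = 0.0167, adjusted p = 0.0667; r = -0.930 without the 2 arrays farthest from the median; 4 relations computed). With the hybridization control level as a covariate the mean shift was 0.066, of opposite sign (camera adjusted p = 0.483). When 1 array was left out, the shift ran from -0.30 without wild-type replicate 3 to -0.13 without wild-type replicate 1. With daDREAM replicate 3 and wild-type replicate 2 both left out it was -0.11 and did not pass (camera adjusted p = 0.0819). A split that crosses the genotypes, wild-type replicates 1 and 2 with daDREAM replicate 1 against the rest, moved the list more. Its shift was 0.28 in size, against 0.19 for the genotypes. The remaining splits of 3 arrays against 3 gave 0.034 to 0.18, so the shift is not particular to genotype.

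**Figure D3:**
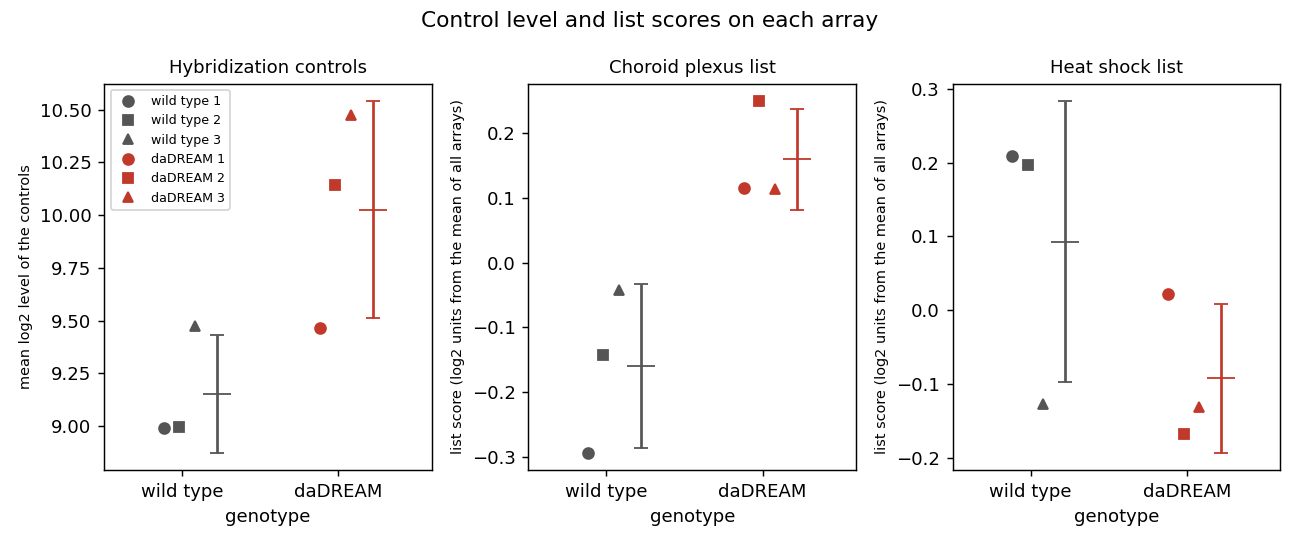
Mean log2 level of the 18 hybridization controls and scores of the choroid plexus and heat shock lists on each array, as points, with the genotype mean and SD (n = 3) beside them. Control levels ran from 8.99 to 10.47, and wild-type replicate 3 and daDREAM replicate 1 lay at 9.48 and 9.47.

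The 36 other lists did not pass, with camera adjusted p from 0.148 to 0.974 and list medians from -0.16 to 0.13. No member of these lists passed limma over all genes or adjusted over the list alone. Purkinje cell markers had 11 of 16 genes lower and a median of -0.02, led by Ppp1r17 at -0.18. Granule cell markers had a median of -0.03, with Barhl1 at 0.28, and astrocyte and Bergmann glia markers a median of -0.00, with the gap junction gene Gja1 at -0.31. In the oligodendrocyte list Ugt8a, an enzyme of myelin galactolipid synthesis, differed by -0.35. Markers of unipolar brush cells had 4 of 5 genes lower, with Sln at -0.23. Interneuron, oligodendrocyte precursor and endothelial markers were led by Grm2 at 0.17, Cspg4 at -0.14 and Flt1 at -0.35.

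The blood, brainstem and forebrain lists did not pass. The most abundant markers were Bpgm at -0.01 for blood, Dbh at -0.10 for brainstem and Ppp1r1b at 0.05 for forebrain. The leading members were Hba-a2, an alpha globin, at 0.29, Chat at -0.37 and Rgs9 at 0.24.

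Calcium and excitability genes were also measured as lists. The calcium pump, exchanger and store list was led by Stim1, a sensor of calcium stores, at 0.26, the calcium-binding list by Ncs1 at 0.42, and the cAMP and CREB list by Crtc1 at 0.20. Voltage-gated calcium, potassium and sodium channel lists were led by Cacna1h at 0.38, Kcnh2 at 0.32 and Fgf14, a sodium channel partner, at -0.35. Receptor lists were led by Grm4 at -0.37 and Gabra5 at 0.38, and the synaptic vesicle list by Syn2 at -0.30. Immediate early genes had 16 of 30 members lower, with Klf4 at 0.28, and the neurotrophin and neuropeptide list was led by Gal at -0.23. The calcium pump list had a median of -0.01 and a mean of 0.01, so its median and test differ in sign.

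Among the remaining pathways, Xbp1 led the unfolded protein response at -0.43 and Bcl2l1 the apoptosis list at 0.60. Ciart led the circadian clock list at 0.45, and the mean difference of that list was 0.087 (camera adjusted p = 0.315). That mean was 0.13 without daDREAM replicate 3 (camera adjusted p = 0.0215) and 0.030 without daDREAM replicate 1 (camera adjusted p = 0.848). The list did not pass in the other runs without 1 array. In 2 settings chosen after seeing the data it passed. Its mean was 0.16 without daDREAM replicate 3 and wild-type replicate 2 (camera adjusted p = 0.0135). With the side of the main gradient as a block it was 0.13 (camera adjusted p = 0.0163). Sult1a1 led the glucocorticoid list at 0.43, Tnc the extracellular matrix list at 0.38, Stard4 the cholesterol list at -0.27 and Igfbp2 the insulin-like growth factor list at 0.58. Oxidative phosphorylation had 36 of 76 genes higher, a median of -0.01 and a mean of 0.01, with Uqcr11 at 0.23, and cytosolic ribosomal proteins had 21 of 46 higher, with Rpl12 at 0.29. The interferon and antigen presentation list was led by H2-D1 at -1.08 (interval -1.93 to -0.23), whose arrays overlapped. The further H2-D1 probe sets with a mean of at least 5 differed by -1.38, -0.57 and 0.73, so their signs disagree. The median of the list, 0.07, and its mean, -0.02, differ in sign, and camera's direction for the list was upward. Among the reference genes Eef2 differed by 0.19, and Uty by -0.07 in the list of Y-linked genes and Xist.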

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

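The tests of genotype and of the hybridization controls as sources of the main gradient, the fits with the hybridization control level as a covariate, the gradient block, the test of exchanged labels and the correlation and single-array tests of the second choroid plexus list were chosen only after the result was seen. Control probe sets that no comparison uses had higher means in daDREAM, with arrays that overlapped between genotypes. The 18 hybridization controls were 0.873 log2 units higher in daDREAM, with array means of 8.99, 8.99 and 9.48 in wild type and 9.47, 10.14 and 10.47 in daDREAM (exact permutation p = 0.2). The 3 control probe sets of 18S ribosomal RNA were 1.00 higher (exact permutation p = 0.3), with wild-type arrays at 6.84, 5.91 and 8.20 and daDREAM arrays at 7.87, 7.81 and 8.27; the gap was 0.462 without wild-type replicate 2 and 1.61 without wild-type replicate 3. The smallest exact p with 3 arrays against 3 is 0.1.

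A single gradient took 57.7% of the variance between the 6 arrays. Its scores overlapped between the genotypes (exact permutation p = 0.6), with wild-type scores of -14.7, -27.8 and 14.7 and daDREAM scores of -47.7, 19.5 and 55.8, which argues against genotype as its whole source. From the lowest score to the highest, the interquartile ranges of the arrays were 3.49, 3.38, 3.27, 3.10, 3.15 and 2.97; these come from the same values as the scores. The hybridization controls followed it with Pearson r = 0.794 (exact permutation p = 0.0639, adjusted p = 0.0852; Spearman rho = 0.771, exact permutation p = 0.103, adjusted p = 0.136), but r was 0.117 without the 2 arrays farthest from the median, so the relation rests on those. The difference between the 3' and 5' control probe sets of 3 transcripts followed it with r = -0.763 (exact permutation p = 0.0875, adjusted p = 0.0875; rho = -0.771, exact permutation p = 0.103, adjusted p = 0.136) and -0.06 without the 2 farthest. Unequal hybridization and RNA degradation may each have a part and cannot be told apart here with 6 arrays.

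The choroid plexus list was the one with the largest mean shift, 0.32. A second list of 34 choroid plexus genes, which shared no gene with the first and was written before its values were looked at, had 24 genes higher and a median of 0.10, at the 99.74th percentile of 10000 random lists matched on mean level. Of the first list 0 genes and of the second 1 stand in another list, and how many cerebellar cells also express is not known here. Random lists do not hold the shared variation of related genes, and for the second list camera gave an unadjusted p of 0.00557 at the preset correlation and 0.169 with an estimated correlation. Its array scores overlapped (exact permutation p = 0.3), and daDREAM replicate 2 alone, at 0.16, lay above all wild-type arrays; the median without it was 0.065, and the percentile was 97.40 without it and 97.39 without wild-type replicate 3. More choroid plexus tissue in the daDREAM samples therefore stays open, as does a change of expression within that tissue, which was not tested. With the main gradient as a covariate the shift was 0.31 ± 0.10 (SE), 0.959 of its size without, which argues against that gradient as the whole source. With the hybridization control level as a covariate it was 0.23 ± 0.15 (SE), against 0.32 ± 0.09 (SE) without a covariate, and no longer passed. Why the call ended was not tested, so unequal hybridization stays open.

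The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 817 probe sets at an unadjusted p under 0.05, and 6 of the 10 splits, the real one included, gave as many, the highest of the others being 14263. That highest split set wild-type replicates 1 and 2 with daDREAM replicate 1 against the rest and gave 3465 calls after adjustment, which points to a structure of the samples that crosses the genotypes. With the side of the gradient as a block, 1891 probe sets were at an unadjusted p under 0.05 and 0 passed after adjustment with limma. For gene lists, the real split gave 5, and 2 of the 10 splits gave as many, the highest other giving 9. That was the split of wild-type replicates 1 and 2 with daDREAM replicate 3 against the rest, which also gave 26 calls after adjustment with limma where the real split gave 0, 1361 probe sets at an unadjusted p under 0.05, and a mean choroid plexus shift of 0.21 in size, against 0.32. With gene-by-gene weights it gave 190 calls and the real split 7510. It is a further structure that crosses the genotypes as labelled, and the split that an exchange of the labels of both replicate 3 arrays would call for. As the gradient split gave more calls, the counts do not decide on such an exchange, which stays open. Over the splits other than the real one the choroid plexus shift was 0.043 to 0.21 in size. Camera at the preset correlation gave it unadjusted p of 8.18e-06, 0.0061, 0.0255, 0.0344 and 0.0430 in some of these and 0.195 to 0.828 in the rest. The real split gave 1.58e-09. A small camera p for this list therefore also arises in groupings that cross the genotypes.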

How the results depend on the processing

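The covariate, gradient and gene-by-gene weight alternatives were chosen after seeing the data. The count of 0 adjusted probe sets held under each alternative except array weights. The planned weights, which did not converge, gave 22291 calls, 25433 probe sets at an unadjusted p under 0.05, 2 lists, and Kcnip3 differences of 0.36 (limma adjusted p = 0.00103) and 0.20 (limma adjusted p = 0.0125). Gene-by-gene weights, added once this was seen, placed 44.1% of the weight on daDREAM replicate 2 and 32.3% on wild-type replicate 1 and gave 7510 calls, 15787 at an unadjusted p and 0.33 for Kcnip3 probe set 1418544_at (limma adjusted p = 0.0375); under the same weights the highest other split gave 7436 calls. The count at an unadjusted p under 0.05, 817, was 466 above the median by mean level, 377 at a mean of at least 6 and 270 with 1 probe set per gene, each with fewer probe sets tested. It was 1361 after renewed quantile normalization, 10471 with the hybridization control covariate and 1891 with the gradient side as a block; the cause was not tested. Leaving out 1 array gave 324 to 7254, the highest without daDREAM replicate 1, and Kcnip3 differences of 0.00 to 0.24 and 0.03 to 0.19. Kcnip3 probe set 1418544_at differed by -0.30 with the covariate and by -0.018 with the gradient block.

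Against 5 lists past camera, 3 passed at a mean of at least 6, all among the 5. With the covariate 3 passed, none of them among the 5, and with the gradient block 9 passed, 4 of them among the 5. None passed with an estimated correlation or with fry (0 each), and 2 to 9 passed when 1 array was left out, the lowest without daDREAM replicate 1 and the highest without daDREAM replicate 3. With the covariate the ependymal list reversed to -0.15 and the heat shock list to 0.066. The cause was not tested. The control level was itself 0.873 higher in daDREAM. Across the genotypes only wild-type replicate 3 and daDREAM replicate 1 lay at a like level, 9.48 and 9.47. The covariate thus shares much of its variation with genotype, so shifts fitted with it are imprecise and their signs decide little. The choroid plexus list passed in 6 of 6 runs without 1 array, with adjusted p from 6.14e-09 to 0.00287. Of the settings that neither left out a single array nor changed the set test, the choroid plexus list passed in 12 of 13, heat shock in 11, microglia in 10, meningeal fibroblast in 9 and ependymal in 6 of 12. Whether the replicate number pairs the arrays cannot be settled with 3 arrays per genotype. Same-numbered arrays correlated at 0.119, -0.281 and 0.323 in their deviations from the group means. Wild-type replicates 1 and 3 correlated best with their own number, and wild-type replicate 2 with daDREAM replicate 1, at 0.488. The replicate block gave 0 calls, 1093 probe sets at an unadjusted p under 0.05 and 5 lists.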

Other observations

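The tests of other probe sets, of chromosomes, of exchanged labels and of H2-D1 as an interferon response were chosen only after the result was seen. Some probe sets were high on some arrays and low on others without following genotype. In 11 probe sets the sorted arrays parted by a gap of at least 1.5 log2 units with at least 2 arrays on each side, and all 11 set wild-type replicates 1 and 2 and daDREAM replicate 3 apart from the other 3 arrays. Rpgrip1, a photoreceptor cilium protein, stood at 9.82, 9.56 and 5.25 in wild type and 5.49, 5.43 and 9.99 in daDREAM. Galc, the lysosomal galactosylceramidase, stood at 7.30, 7.33 and 4.05 in wild type and 3.99, 4.36 and 6.37 in daDREAM. The others with a gene name were Arhgap26, Mtmr7, Soga3, Tia1, Fam126b and Mid1, and 3 have none here. All were singled out after their values were seen. The 8 named genes lie on 8 chromosomes and part the arrays in the same way. For these genes this argues against alleles that segregate mouse by mouse in a mixed background, which would part the arrays in several ways. The rule of at least 2 arrays on each side could not find an allele that sets a single array apart. Such alleles in other genes are therefore not covered. The same parting of the arrays gave 26 probe sets past the adjusted limma threshold and 9 gene lists past camera, where the genotypes as labelled gave 0 and 5. These counts are drawn from the same values as the 11 probe sets, so they are no separate support. The split of wild-type replicates 1 and 2 with daDREAM replicate 1 against the rest gave 3465 calls. An exchange of the labels of both replicate 3 arrays stays open, as does a difference of strain between whole sets of mice, which was not tested.

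H2-D1, a class I histocompatibility gene, also varied within genotypes: in daDREAM replicate 1 its 4 probe sets deviated from the group mean by -1.46, -0.66, -0.80 and 0.73. An interferon response would move them one way, and the smaller of the largest rise and the largest fall was 0.733. In the same array the 16 interferon genes outside H2 had a median difference of -0.29 from the other daDREAM arrays, and both H2-K1 probe sets were at their lowest, 5.90 and 6.26, so a weaker interferon response there stays open. For the 11 probe sets, the 10 other probe sets of 5 of the genes had a median SD over the arrays 0.208 of that of the probe set that parted, and the highest ratio was 0.529, in Fam126b. The 11 were chosen for a wide gap, which lowers this ratio by itself, so it leaves a variant inside the probed stretch undecided. Among 12 other H2 probe sets, 16.7% had a within-group SD above the 95th percentile of probe sets of like mean, which leaves a strain difference in the histocompatibility region undecided. Genotype, the factor of the design, was not tested as a source, since the pattern crosses it as labelled.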
